A study of Mus musculus with 19 samples.

How the data were processed

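The data were 19 Agilent 2-colour mouse arrays scanned with Feature Extraction 9.5.3.1, with liver RNA in Cy5 and a reference RNA in Cy3 on every array and no dye swap, so dye and sample type could not be separated. Per the file headers, the scanner files gave mean and median signals and local backgrounds as intensity values on a linear scale, and a log ratio in log10 of processed Cy5 over processed Cy3. Those processed signals had been background-subtracted and dye-normalized (linear and lowess) by Feature Extraction. The deposited per-array tables of the authors gave raw and normalized signals as intensity values and their quotient as a ratio. The deposited series table held the log2 of the authors' ratio within rounding, and the authors' normalization method was not stated. The analysis started from the scanner files.

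Each array held 43379 gene spots for 41174 probes, besides 1639 control spots. Of the probes, 22951 were named by accession, 6659 by symbol and 3105 by synonym in a reference table of mouse genes (GRCm38.p6), and 8459 kept the name in the file, which gave 27672 distinct genes. Positions, per the file headers, were on mm7 and were used only as printed. Mean signals were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, turned into log2 ratios and normalized by loess within each array. Repeated spots were averaged. A probe was kept if it was well above background in Cy5 on at least 4 of the 19 arrays, which left 23144 probes, and the brightest in Cy5 stood for each of 15728 genes, of which 157 lacked a value on some array.

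A linear model with the 4 groups and the slide as a fixed term was fitted with lmFit and eBayes (10 residual degrees of freedom, 4.84 prior degrees of freedom). Tests were two-sided with Benjamini and Hochberg adjustment within each comparison, and an adjusted p under 0.05 counted as past the threshold. The slide and the scan could not be separated, because each slide was scanned once. The 31 gene lists were tested over 15571 genes with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. The preset test called 10, 10, 9 and 10 lists (4 h, 24 h, difference of effects, control time). In other splits of the arrays it called a median of 8, 6, 6 and 6, so the number of list calls did not exclude chance. Groups, settings and the rule for named genes were set before the data were examined. For each BaP comparison the rule named the 10 largest increases and the 10 largest decreases past the threshold that had a gene symbol and every BaP array beyond the control mean. It always named Cyp1a1, Cyp1a2, Cyp1b1, Nqo1, Cdkn1a, Mdm2, Ccng1 and Bax, and of each list up to 4 members past the threshold, those with the largest change. For the other comparisons it named the 5 largest past the threshold in each direction and list members by the same rule. Acaca and Acot3 at 4 h and Cyp2a5 at 24 h were named besides, after their values were seen. Replicate numbers were not used as pairs: as normalized, the correlation between control and BaP arrays of the same number lay between 0.196 and 0.678 where they shared a slide and between -0.099 and 0.180 where they did not. Some genes that met the naming rules are not reported here.

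Tested on simulated data with 200 changed genes among 15571, a change of 1 on the log2 scale was recovered in 98.5% (4 h), 94.1% (24 h), 88.7% (difference of effects) and 98.5% (control time), and one of 0.5 in 72.4%, 65.6%, 38.3% and 57.4%. The false share lay between 2.5% and 7.1%. A list of 20 genes shifted by 0.5 was called by camera and fry in all 4 comparisons, and 0 of 30 unshifted lists were called. The simulated noise was independent between genes, so false calls among lists of correlated genes were not tested.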

Results

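Liver RNA was measured in male B6C3F1 mice aged 27 to 30 days that received corn oil or 150 mg/kg benzo(a)pyrene (BaP) daily for 3 days and were killed 4 h or 24 h after the last dose. BaP is a polycyclic aromatic hydrocarbon, and corn oil was the vehicle. The 19 arrays, 1 per mouse, fell into 4 groups, with 5 control and 5 BaP arrays at 4 h and 4 control and 5 BaP arrays at 24 h. Each array held liver RNA in the Cy5 channel and a universal mouse reference RNA, pooled from 11 cell lines, in the Cy3 channel, so every value was a log2 ratio of liver to reference. The arrays sat on 6 slides, and each slide held at least 2 of the 4 groups. Per array, between 48.5% and 56.0% of the probes were well above background in Cy5 and between 52.9% and 63.9% in Cy3. The median Cy5 signal lay between 70.2 and 89.8 scanner units over a background of 58.0 to 61.0. The number of arrays limited the precision: the median standard error of a log2 fold change was 0.092 at 4 h and 0.094 at 24 h. Values below are log2 fold changes with standard errors, from limma, with the slide as a term.

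The first comparison asked what 3 doses of BaP had changed in the liver 4 h after the last dose. Cyp1a1, a cytochrome P450 that oxidises polycyclic aromatic hydrocarbons, was 137-fold higher (log2 7.10 ± 0.25, adjusted p = 1.4e-09, n = 4 BaP values and 5 control arrays). It was higher on 4 of 4 BaP arrays that gave a value. Control arrays were above background for Cyp1a1 on 2 of 5, so its fold rested on control values near the background and is not an exact size. In the Cy5 channel alone Cyp1a1 rose by 8.20 on the log2 scale, because the reference signal at its probe also rose. Fmo2, a flavin-containing monooxygenase, was 4.67-fold higher (2.22 ± 0.24, adjusted p = 6.2e-05) and Nqo1, a quinone reductase, was 4.18-fold higher (2.06 ± 0.12, adjusted p = 1.7e-07), each on 5 of 5 BaP arrays. Fasn, the fatty acid synthase, fell by 1.33 ± 0.26 on the log2 scale (adjusted p = 0.0063). Hmgcs1, an early enzyme of cholesterol synthesis, fell by 1.33 ± 0.21 (adjusted p = 0.0016). The clock output gene Dbp fell by 1.98 ± 0.23 (adjusted p = 0.00012). The array annotation placed the Cyp1a1 probe on mm7 chromosome 9 from 57731394 to 57731453 and the Nqo1 probe on chromosome 8 from 105988683 to 105988742.

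Of 19 measured target genes of the aryl hydrocarbon receptor (AhR), the receptor that BaP activates, 12 rose, 1 fell and 6 did not pass. Adjusted over the list alone, 15 rose and 1 fell. Besides Cyp1a1, Fmo2 and Nqo1, those that rose included Cyp1b1 (1.03 ± 0.21). Their median was 1.13 and the list rose as a set, over the 15 members with a value on every array, which left out Cyp1a1 (adjusted p = 2.2e-15, and adjusted p = 0.00061 with an estimated correlation). The member that fell in the ratio was Cyp1a2, by 0.60 ± 0.13 (adjusted p = 0.012). Its direction turned to 2.79 in the Cy5 channel alone, to 0.18 with median centring in place of loess and to 0.51 in the authors' own ratios. In that table the reference channels of 2 arrays looked exchanged. These were remade from their own raw median signals by loess without background correction, while the other arrays kept the authors' normalization. With this setting, added after seeing the data, Cyp1a2 was at -0.45 (adjusted p = 0.036). The reference channel alone rose by 3.40 at the Cyp1a2 probe and by 1.10 at the Cyp1a1 probe, both after loess. Median centred without loess, the Cyp1a2 probe rose by 3.09 in Cy3 and by 3.24 in Cy5. Of 28 measured Nrf2 targets, genes of the response to electrophiles and oxidants, 15 rose and none fell. Adjusted over the list alone, 21 rose and 1 fell. They included Gsta2 (2.10 ± 0.25) and Gsta1 (1.79 ± 0.28), both glutathione transferases that are also in the AhR list with Nqo1, and Cbr3, a carbonyl reductase (2.00 ± 0.14). The Nrf2 list rose as a set with a median of 0.43 (adjusted p = 2.3e-20, and adjusted p = 0.00061 with an estimated correlation).

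**Figure D1:**
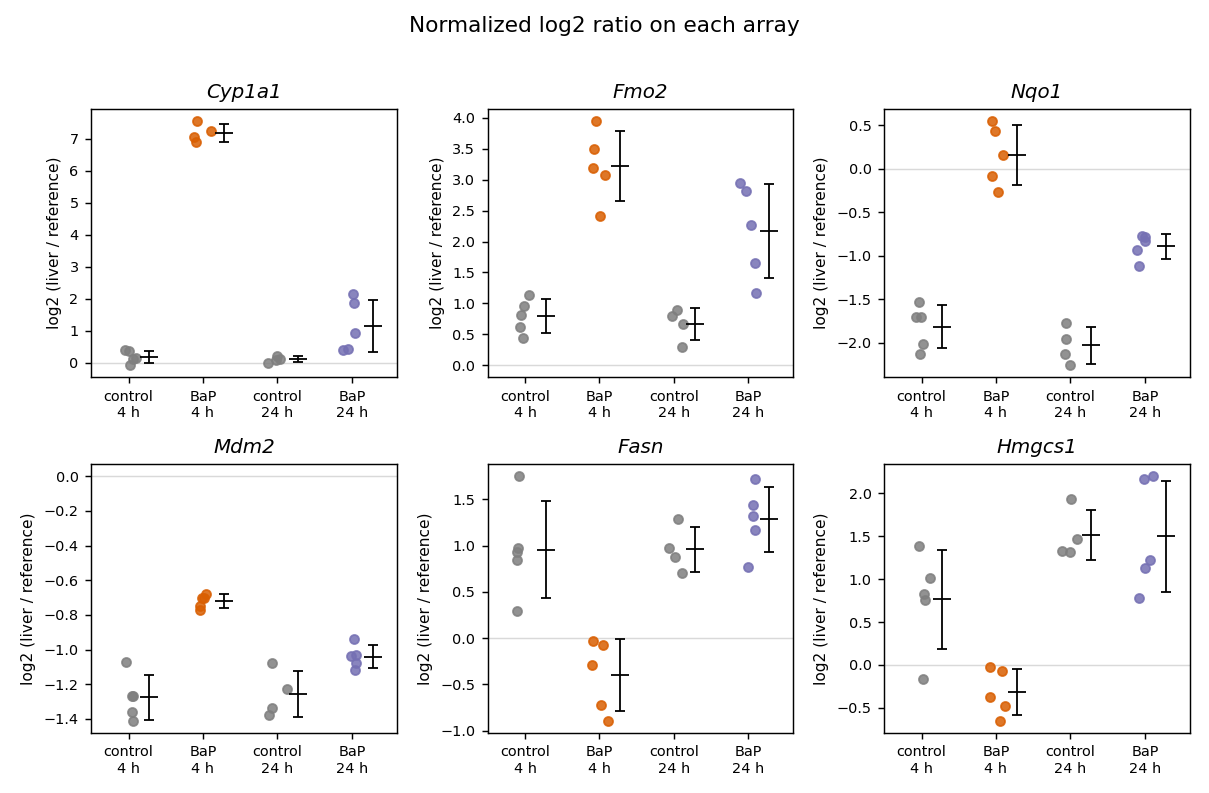
Normalized log2 ratio of liver to reference RNA (vertical axis) for 6 genes in the 4 groups (horizontal axis); each dot is 1 array and the bars show mean and SD. Cyp1a1 on the BaP arrays lay between 6.90 and 7.56 at 4 h and between 0.42 and 2.16 at 24 h, against -0.07 to 0.41 on the controls at 4 h; Fmo2 lay between 1.17 and 2.95 on the BaP arrays at 24 h.

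**Figure D2:**
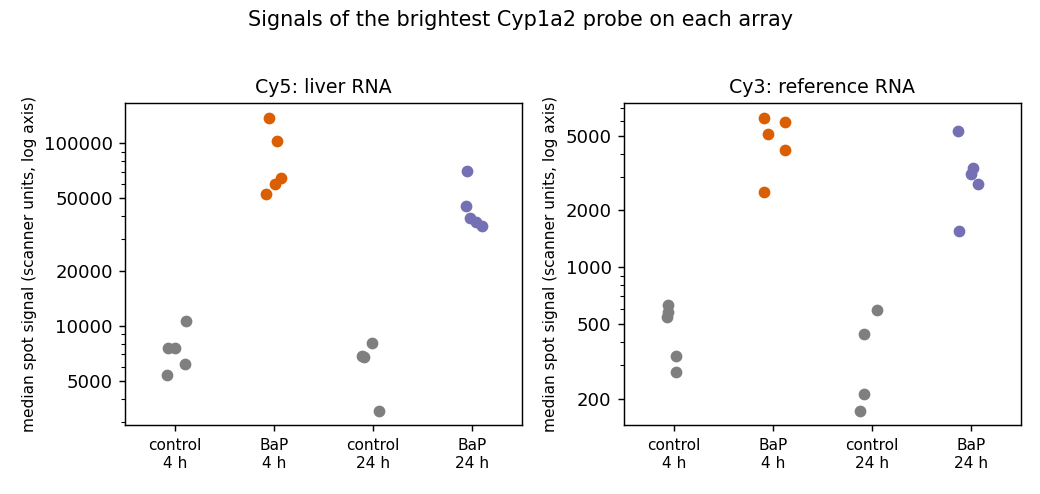
Scanned median signal of the brightest Cyp1a2 probe (vertical axes, scanner units, log scale) in the Cy5 channel with liver RNA and the Cy3 channel with reference RNA, 1 dot per array in 4 groups. At 4 h the Cy5 signal lay between 5380 and 10722 on the controls and between 52517 and 137643 on the BaP arrays, while the Cy3 signal lay between 276 and 630 and between 2521 and 6205.

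Targets of the nuclear receptors CAR and PXR, which control drug metabolism, rose on balance at 4 h. Of 21 measured, 7 rose and none fell (9 and 0 adjusted over the list alone). Among them were Cyp2b13 (1.72 ± 0.34), Cyp2b10 (1.45 ± 0.29), Por, the reductase that supplies cytochromes P450 with electrons (1.29 ± 0.20), and Sult1e1, the oestrogen sulfotransferase (1.09 ± 0.22). The set test gave adjusted p = 2.3e-07, but adjusted p = 0.17 with an estimated correlation. Of 33 measured conjugation enzymes 7 rose and 2 fell (8 and 2 adjusted over the list alone), with Ugt1a9 at 1.50 ± 0.14, Sult1d1 at 1.40 ± 0.34 and Ugt2b35 at 1.27 ± 0.17. That set had adjusted p = 0.002, adjusted p = 0.41 with an estimated correlation, 0.18 after scaling between arrays and 0.33 in the scanner software's log ratios. Of 17 female-biased liver genes 5 rose and none fell (6 and 0 adjusted over the list alone; adjusted p = 6.4e-05, adjusted p = 0.17 with an estimated correlation). Among them were Fmo2, which the AhR list also holds, Cyp2b13 and Cyp2b10, which the CAR and PXR list also holds, and Acot3 (1.34). The female-biased call was lost in the scanner software's log ratios (0.086) and with only probes above background on all 19 arrays (0.30).

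Some genes of lipid synthesis fell at 4 h. Of 20 measured genes of fatty acid and triglyceride synthesis none rose and 5 fell (0 and 10 adjusted over the list alone). They were Fasn, Srebf1, the transcription factor that drives the pathway (-0.83 ± 0.12), Pklr (-0.66 ± 0.13), Gpam (-0.61 ± 0.15) and Acaca (-0.59). The set test gave adjusted p = 5.9e-06, but adjusted p = 0.17 with an estimated correlation. Of 25 cholesterol synthesis genes 1 rose and 7 fell (1 and 10 adjusted over the list alone), including Hmgcs1, Stard4 (-0.92 ± 0.13), Msmo1 (-0.86 ± 0.18) and Idi1 (-0.67 ± 0.16). That set had adjusted p = 1.8e-05, but adjusted p = 0.41 with an estimated correlation. Its median within single slides that held both groups lay between -0.49 and 0.02. Interferon response genes fell too, 5 of 21 with none higher (11 lower and 1 higher adjusted over the list alone). Rsad2 was at -0.62 ± 0.12, Irf7 at -0.49 ± 0.14 and Oas1a at -0.38 ± 0.09 (adjusted p = 0.00016, adjusted p = 0.17 with an estimated correlation).

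Of 30 measured p53 targets, the genes that respond to DNA damage through p53, 4 rose at 4 h and none fell (6 and 1 adjusted over the list alone). They were Trp53inp1 (0.98 ± 0.15), Ddit4l (0.84 ± 0.15), Mdm2, the ubiquitin ligase of p53 (0.58 ± 0.07, adjusted p = 0.00017, higher on 5 of 5 BaP arrays), and Ccng1 (0.41 ± 0.10, adjusted p = 0.022). Cdkn1a, the cell cycle inhibitor p21, was at 0.55 ± 0.22 and did not pass (adjusted p = 0.18). Bax was at -0.17 ± 0.14 (adjusted p = 0.58), with a sign that turned in 4 other settings, among them the Cy5 channel alone (0.08). The median of the p53 list was 0.02 and its set test had adjusted p = 0.027, adjusted p = 0.17 with an estimated correlation, 0.06 without BaP_24h replicate 12 and 0.052 without BaP_24h replicate 14. The p53 call was also lost in 5 other settings, with an adjusted p of up to 0.21 in a fit of the 2 groups alone. One of them was the authors' ratios (0.081), where it was kept with the 2 arrays remade (0.047). In the heat shock and metallothionein list 1 of 10 rose, the chaperone Hspa8 (0.63 ± 0.16), while 2 rose adjusted over the list alone (set adjusted p = 0.00065, adjusted p = 0.17 with an estimated correlation).

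The clock list had 6 of 20 members higher and 3 lower at 4 h (8 and 3 adjusted over the list alone) with no call as a set (adjusted p = 0.20). Arntl, a core activator of the clock, rose by 1.42 ± 0.25 and Per1 by 1.00 ± 0.26, while Nr1d1, a repressor of Arntl, fell by 2.05 ± 0.26. Other genes with large changes were Olfr114 (2.90 ± 0.17), Tsku (2.02 ± 0.18) and the transcription factor Myc (1.99 ± 0.33), which rose. Rgs16 (-2.17 ± 0.50), E2f8 (-1.95 ± 0.29), Arrdc3 (-1.77 ± 0.32), Slc25a30 (-1.72 ± 0.43), Mid1ip1 (-1.55 ± 0.18), Tsc22d1 (-1.48 ± 0.21) and Raet1a (-1.44 ± 0.35) fell. Hsd3b4 fell by 1.63 ± 0.25, but was at 0.04 in the scanner software's log ratios.

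Among the lists with no call as a set at 4 h, the fatty acid oxidation and PPARa list had 3 of 34 members higher and 2 lower (adjusted p = 0.38). Pdk4 was at 1.50 ± 0.17, Acot1 at 0.63 ± 0.16, Vnn1 at -1.18 ± 0.20 and Plin2 at -0.97 ± 0.13. The bile acid list had 1 of 24 higher and 3 lower (adjusted p = 0.85). Abcc3 was at 0.74 ± 0.13, Nr0b2 at -0.99 ± 0.19, Hsd3b7 at -0.60 ± 0.10 and Amacr at -0.54 ± 0.09. Glucose metabolism (1 of 22 higher, 1 lower, adjusted p = 0.71, median -0.11 and mean 0.02) held Ppp1r3b at 1.10 ± 0.17 and Pklr. The acute phase list (2 of 30 higher, adjusted p = 0.62, median -0.05 and mean 0.10) held the transcription factors Cebpd at 1.19 ± 0.25 and Cebpb at 0.73 ± 0.13. The list of the unfolded protein and integrated stress response (2 of 19 higher, 1 lower, adjusted p = 0.20) held Herpud1 at 0.67 ± 0.15, Trib3 at -0.99 ± 0.19 and Sel1l at 0.33 ± 0.09, with -0.01 at another Sel1l probe. DNA repair had 1 of 33 higher, Ercc3 (0.31 ± 0.09), and 1 lower (adjusted p = 0.85; the median was -0.03 while the set test leaned up). Of 33 cell cycle genes, Ccne1 (-0.59 ± 0.12) passed (adjusted p = 0.39). Male-biased liver genes had 1 of 19 higher, Nat8f5 (1.77 ± 0.19), and 1 lower, Nudt7 (-0.75 ± 0.14; adjusted p = 0.43).

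No cell type list was called as a set at 4 h. Of 17 pericentral hepatocyte markers 3 fell, Tbx3 (-1.24 ± 0.26), Lgr5 (-0.68 ± 0.15) and Nkd1 (-0.55 ± 0.12; set adjusted p = 0.38). None of 18 periportal markers (adjusted p = 0.71) and none of 15 general hepatocyte markers (adjusted p = 0.38) passed. Endothelial markers split, with Lyve1 at 0.82 ± 0.16, Emcn at 0.51 ± 0.09, Oit3 at -0.65 ± 0.09 and Eng at -0.34 ± 0.09 among 18 (adjusted p = 0.71). The transferrin receptor Tfrc rose by 1.58 ± 0.11 as 1 of 7 erythroid markers (adjusted p = 0.71; median -0.12, mean 0.06). Single members also passed among the Kupffer cell markers (Lyz2, -0.39 ± 0.08; 18 members, adjusted p = 0.31) and the lymphocyte markers (Ighm, -0.55 ± 0.15; 20 members, adjusted p = 0.42). Among 4 neutrophil and monocyte markers Ly6c1 rose (0.61 ± 0.15, with -0.17 at its other probe; adjusted p = 0.55). Of 7 adipose markers Fabp4 rose (0.61 ± 0.13) and Lipe fell (-0.36 ± 0.10; adjusted p = 0.43). None of the 19 stellate cell (adjusted p = 0.79), 13 cholangiocyte (adjusted p = 0.62) and 5 pancreatic acinar markers (adjusted p = 0.62) passed.

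Lists without a call at 4 h were called in some settings. Fatty acid oxidation fell after scaling (0.048) and in the Cy5 channel alone (0.033), pericentral markers fell after scaling (0.032), and cell cycle genes fell with the replicate block (0.03) and in the fit of 2 groups (0.0023). The unfolded protein list rose with array weights (0.033). With 1 array left out, the unfolded protein list rose without control_4h replicate 6 (0.027) or control_4h replicate 7 (0.036) and the clock list without control_4h replicate 5 (0.033). Hepatocyte markers fell without control_4h replicate 2 (0.017), and Kupffer cell markers without BaP_4h replicate 2 (0.048). In all, limma called 1002 of 15728 genes at 4 h, 457 higher and 545 lower, with 65 at least 2-fold higher and 33 at least 2-fold lower. Among the 78 named genes past the threshold, 73 were beyond the control mean on every BaP array. For the 19 named for the size of their change the naming rule required this, and of the other 59 it held for 54. Of the 78, 77 moved the same way on all 3 slides that held both groups, the exception being Acot1. All 78 had been put past the threshold by these same arrays, so these counts are not independent support. Without the slide term 514 genes passed, and leaving out 1 array gave 592 (control_4h replicate 2), 660 (control_4h replicate 5) or 581 (BaP_4h replicate 5), with no other array moving the count by more than 1.5 times. Across all settings other than leaving out 1 array, 8 of the 78 kept their call (Cbr3, Cyp1a1, Fmo2, Nqo1, Pdk4, Tfrc, Tsc22d1 and Tsku). Median centring kept 15 and the fit with no slide term 48. With each array left out in turn, 53 of the 78 stayed past the threshold every time. The highest adjusted p among the other 25 (Acot1, Ccne1, Ccng1, Cyp1a2, Eng, Ercc3, Fabp4, Gpam, Gstt3, Herpud1, Hspa8, Idi1, Ighm, Irf7, Lgr5, Lipe, Ly6c1, Nkd1, Oas1a, Per1, Raet1a, Rgs16, Sel1l, Slc25a30 and Sult1d1) was 0.18, for Ighm without control_4h replicate 5.

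The second comparison asked the same at 24 h after the last dose. Fmo2 was still 2.87-fold higher (log2 1.52 ± 0.24, adjusted p = 0.0039, n = 5 BaP and 4 control arrays, higher on 5 of 5). Cyp1a1 was at 0.91 ± 0.25 and did not pass (adjusted p = 0.067). The controls were above background for it on 0 of 4 arrays and the BaP arrays on 5 of 5, which made it at least 2.03-fold higher than the background level. Nqo1 was 2.04-fold higher (1.03 ± 0.12, adjusted p = 0.00064). Dbp rose by 2.38 ± 0.23 (adjusted p = 0.00017) and Arntl fell by 1.85 ± 0.26 (adjusted p = 0.0017), the reverse of 4 h. Lss, an enzyme of cholesterol synthesis, rose by 0.80 ± 0.17 (adjusted p = 0.018).

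Of 20 clock genes, 10 rose and 3 fell at 24 h (11 and 3 adjusted over the list alone), with a median of 0.59. Besides Dbp, its relative Tef (1.69 ± 0.23) and the clock-controlled protease Usp2 (2.16 ± 0.30) rose. BaP_24h replicate 9 lay nearer the controls than the other BaP arrays for Dbp (-0.74 against 0.54 to 0.95), and Arntl on it was at 0.93, close to the lowest control (0.96). Without it the changes were 2.68 for Dbp, -2.17 for Arntl, 2.00 for Tef and 2.46 for Usp2. The set test gave adjusted p = 1.8e-06, but adjusted p = 0.13 with an estimated correlation. The labels gave no hour of killing, so a difference in hour between the arms was not excluded for the clock genes. Of 25 cholesterol synthesis genes 6 rose and none fell (11 and 1 adjusted over the list alone), among them Lss, Mvk (0.68 ± 0.17) and Nsdhl (0.68 ± 0.15, with -0.19 at another of its probes). That set had adjusted p = 3e-07, but adjusted p = 0.32 with an estimated correlation. Its median within single slides that held both groups lay between -0.05 and 0.60.

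The AhR list had 6 of 19 members higher and 1 lower at 24 h (9 and 2 adjusted over the list alone; median 0.25). The Nrf2 list had 8 of 28 higher and 2 lower (11 and 3 adjusted over the list alone; median 0.22). Both rose as sets, the AhR list with adjusted p = 1e-04 and adjusted p = 0.13 with an estimated correlation, the Nrf2 list with adjusted p = 0.0015 and adjusted p = 0.16 with an estimated correlation. Fmo2, Gsta2 (1.32 ± 0.26) and Gsta1 (1.28 ± 0.28) rose, while Gclc, a subunit of the enzyme that starts glutathione synthesis, and Me1 fell (-0.70 ± 0.16 and -0.59 ± 0.09). Cyp1a2 was again lower in the ratio, by 0.66 ± 0.14 (adjusted p = 0.014), but at 2.81 in the Cy5 channel alone, 0.46 in the authors' ratios (-0.70 with the 2 arrays remade) and 0.12 at its other probe. Cyp2a5, another member, was at -0.01 in the ratio while each channel alone rose by 2.00. Cyp1b1 was at 0.10 ± 0.22 (adjusted p = 0.88), and at -0.03 without control_24h replicate 9 and -0.02 without BaP_24h replicate 9. Of 30 p53 targets 2 rose and none fell (4 and 1 adjusted over the list alone), Dcxr, a carbonyl reductase (0.68 ± 0.09), and Ccng1 (0.48 ± 0.10). Its set test had adjusted p = 0.015, adjusted p = 0.16 with an estimated correlation, 0.089 without control_24h replicate 9, 0.086 without BaP_24h replicate 9, 0.054 without control_24h replicate 13, 0.07 in the authors' ratios (0.035 with the 2 arrays remade) and 0.057 with median centring. Mdm2 (0.16 ± 0.07, adjusted p = 0.25), Bax (0.22 ± 0.14, adjusted p = 0.46) and Cdkn1a (0.10 ± 0.23, adjusted p = 0.88) did not pass, and Cdkn1a was at -0.02 in the Cy5 channel alone.

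Female-biased liver genes rose at 24 h (4 of 17 higher and 1 lower, 8 and 2 adjusted over the list alone; adjusted p = 1.3e-05, adjusted p = 0.16 with an estimated correlation). Among the members that rose were Fmo2, Cyp4a14, a fatty acid hydroxylase that the PPARa list also holds (2.14 ± 0.28), and Acot3 (1.65 ± 0.33); the call was lost with only probes above background on all 19 arrays (0.18). Male-biased liver genes fell (none of 19 higher and 2 lower, 0 and 5 adjusted over the list alone; adjusted p = 0.00013, adjusted p = 0.45 with an estimated correlation). Elovl3, a fatty acid elongase, was at -0.95 ± 0.21 and Cyp2u1 at -0.57 ± 0.13. At the Elovl3 probe the reference channel alone fell by 3.56 and the Cy5 channel alone was at -4.51 (adjusted p = 0.0017). General hepatocyte markers fell in the same comparison (1 of 15 lower, Ttr, -0.67 ± 0.16; 8 lower adjusted over the list alone). The hepatocyte set had a median of -0.38, adjusted p = 6.3e-05, adjusted p = 0.45 with an estimated correlation and adjusted p = 0.34 in the Cy5 channel alone. Periportal markers fell as a set with no single member past the threshold (7 of 18 lower adjusted over the list alone; adjusted p = 0.0034, adjusted p = 0.59 with an estimated correlation). The periportal call was lost without BaP_24h replicate 10 (0.10) or control_24h replicate 10 (0.089). It was also lost in the authors' ratios (0.53, but 0.00066 with the 2 arrays remade), after scaling between arrays (0.18) and in the Cy5 channel alone (0.23). The glucose metabolism list fell (1 of 22 lower, G6pc, the last step of glucose release, -0.81 ± 0.16; 2 higher and 5 lower adjusted over the list alone; adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation). Its direction turned in the Cy5 channel alone (adjusted p = 0.99). The glucose call was lost without control_24h replicate 10 (0.21), control_24h replicate 9 (0.08), BaP_24h replicate 9 (0.077) or BaP_24h replicate 10 (0.068). It was lost as well in the authors' ratios (0.63, but 0.035 with the 2 arrays remade), after scaling (0.33), in the scanner software's log ratios (0.052) and with the mean of all probes (0.051).

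Among other genes with large changes at 24 h, Olfr114 (2.75 ± 0.17), the monocarboxylate carrier Slc16a5 (2.05 ± 0.22) and Por (1.72 ± 0.21) rose. Bcl6 (-1.97 ± 0.35), Spon2 (-1.59 ± 0.21), Lpl (-1.45 ± 0.26), Clpx (-1.42 ± 0.18), Insig2 (-1.42 ± 0.26), Slc30a10 (-1.35 ± 0.20), Lrfn3 (-1.34 ± 0.24) and Adgrv1 (-1.32 ± 0.14) fell. Bcl6 is a transcriptional repressor, Lpl the lipoprotein lipase and Insig2 a brake on cholesterol synthesis. The metallothioneins Mt2 (1.76 ± 0.41) and Mt1 (1.69 ± 0.29) were the 2 of 10 heat shock and metallothionein genes that rose (set adjusted p = 0.34). Sets without a call at 24 h included CAR and PXR targets (3 of 21 higher, 1 lower, adjusted p = 0.086; Cyp2c38 0.82 ± 0.19, Cyp2c55 -0.65 ± 0.15). The CAR and PXR list was called, as higher, in 5 other settings, with adjusted p from 5.8e-05 (Cy5 channel alone) to 0.037 (no filter on dim probes), in the authors' ratios (0.0013, but not with the 2 arrays remade), and without control_24h replicate 9 (0.0098) or BaP_24h replicate 9 (0.049). Conjugation enzymes had no call (5 of 33 higher, adjusted p = 0.15; Ugt1a9 1.26 ± 0.14, Gstt2 0.94 ± 0.14, Gstt3 0.93 ± 0.20), but were called as higher in the authors' ratios (0.018, but not with the 2 arrays remade), after scaling (0.016) and in the Cy5 channel alone (0.0046). Fatty acid and triglyceride synthesis (1 of 20 higher, 3 lower, adjusted p = 0.28) had Srebf1 at 0.64 ± 0.13, Elovl5 at -0.78 ± 0.12 and Scd1 at -0.71 ± 0.17. The PPARa list (3 of 34 higher, 2 lower, adjusted p = 0.40) had Cyp4a31 at 0.98 ± 0.16 and Pdk4 at -0.84 ± 0.17. The bile acid list (2 of 24 higher, 1 lower, adjusted p = 0.68) had Akr1d1 at 0.78 ± 0.16. The acute phase list (1 of 30 higher, 1 lower, adjusted p = 0.90) had Orm3 at 1.54 ± 0.40 and Saa2 at -0.51 ± 0.11. Saa2 turned to 0.34 in the authors' ratios (-0.50 with the 2 arrays remade) and 1.35 in the Cy5 channel alone. The remaining metabolic, stress and proliferation sets were interferon response (Rsad2, -0.83 ± 0.12, lower among 21; adjusted p = 0.81) and the unfolded protein list (Sel1l, -0.36 ± 0.10, lower among 19; adjusted p = 0.26). The others were cell cycle (Tk1, 0.69 ± 0.12, and Mcm7, -0.46 ± 0.12, among 33; adjusted p = 0.88; median -0.05, test up) and DNA repair (0 of 33; adjusted p = 0.40).

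Cell type markers other than the hepatocyte lists had no call as a set at 24 h. Hba-a1, a haemoglobin chain (-1.10 ± 0.22), and Slc4a1 (-0.38 ± 0.08) fell among 7 erythroid markers (adjusted p = 0.77). Ly6c1 rose by 1.02 ± 0.15, with -0.04 at its other probe, as 1 of 4 neutrophil and monocyte markers (adjusted p = 0.097), and Lyz2 fell by 0.43 ± 0.08 as 1 of 18 Kupffer cell markers (adjusted p = 0.68). Among lists without a call, the unfolded protein list was called as lower in the authors' ratios (0.019, but not with the 2 arrays remade) and without control_24h replicate 9 (0.028) or BaP_24h replicate 9 (0.026), and the neutrophil list as higher without control_24h replicate 12 (0.04). Acute phase (0.00016) and pericentral (0.00039) lists were called as higher in the Cy5 channel alone. In the fit of 2 groups the cell cycle (0.0089) and neutrophil (0.032) lists were called as higher. With no slide term both were called as higher (0.001 and 0.044), and the PPARa (0.023), Kupffer, bile acid and endothelial lists (0.049 each) as lower. None passed among the endothelial (18 members, adjusted p = 0.40), pericentral (17, adjusted p = 0.88), lymphocyte (20, adjusted p = 0.88), stellate (19, adjusted p = 0.88), cholangiocyte (13, adjusted p = 0.88), acinar (5, adjusted p = 0.77) and adipose markers (7, adjusted p = 0.67).

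**Figure D3:**
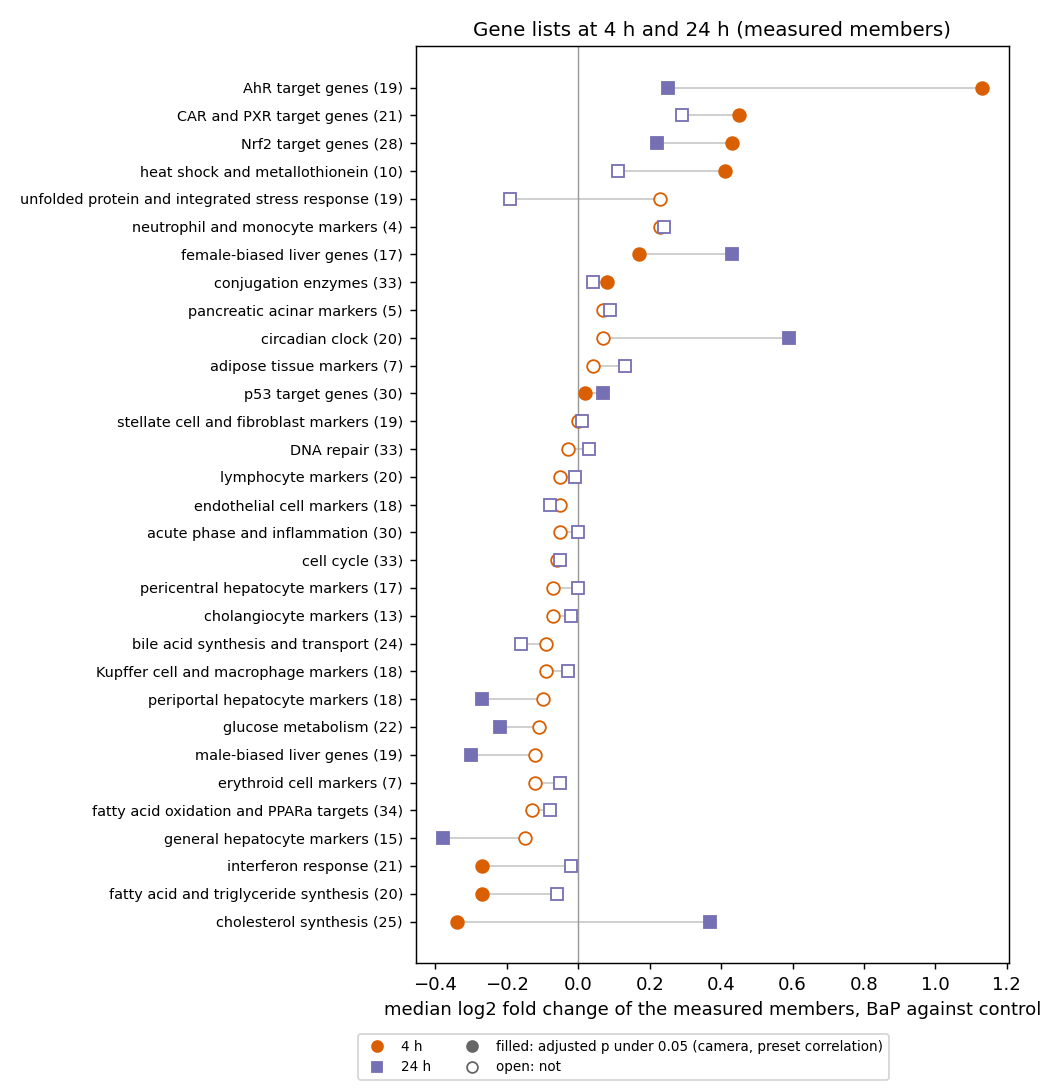
Median log2 fold change, BaP against control, of the measured members (their number in parentheses) of the 31 gene lists at 4 h (circles) and 24 h (squares); filled symbols mark an adjusted p under 0.05 in the camera test with a preset correlation. The AhR list lay at 1.13 and 0.25, and the cholesterol synthesis list at -0.34 and 0.37. The direction of glucose metabolism at 24 h turned in the Cy5 channel alone. This test called 10 lists at 4 h and 10 at 24 h, against a median of 8 and 6 in other splits of the arrays.

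At 24 h limma called 532 of 15727 genes, 244 higher and 288 lower, with 40 at least 2-fold higher and 19 at least 2-fold lower. Of the 60 named genes past the threshold, 53 were beyond the control mean on every BaP array. For the 18 named for size the naming rule required this, and of the other 42 it held for 35. Of the 60, 58 moved the same way on all 3 slides with both groups, the exceptions being Mt2 and Sel1l. All 60 had been put past the threshold by these same arrays, so these counts are not independent support. Without the slide term 213 genes passed, a fit of these 2 groups alone gave 1, and leaving out 1 array gave 268 (control_24h replicate 10), 276 (BaP_24h replicate 10), 233 (BaP_24h replicate 12) or 268 (control_24h replicate 12). Across all settings other than leaving out 1 array, 0 of the 60 kept their call. Median centring kept 6, the fit with no slide term 32 and the fit of 2 groups 1. With each array left out in turn, 31 of the 60 stayed past the threshold every time. The highest adjusted p among the other 29 (Abcc3, Acot3, Akr1d1, Ccng1, Cyp1a2, Cyp2c38, Cyp2c55, Cyp2u1, Elovl3, G6pc, Gclc, Gsta1, Gsta2, Gstm1, Gstt3, Hba-a1, Lss, Mcm7, Mt2, Mvk, Nsdhl, Orm3, Pdk4, Plin2, Saa2, Scd1, Sel1l, Slc4a1 and Ttr) was 0.17, for Orm3 without BaP_24h replicate 12.

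Whether the effect of BaP differed between the times was tested as a difference of the effects. Cyp1a1 on the BaP arrays lay between 6.90 and 7.56 at 4 h and between 0.42 and 2.16 at 24 h. Its difference of effects passed (adjusted p = 1.6e-06) but had no exact size, because the 24 h controls were not well above background. Dbp (4.36 ± 0.34, adjusted p = 1.4e-05) and Arntl (-3.27 ± 0.37, adjusted p = 3e-04) differed most among the clock genes. Of these, 7 of 20 had a higher and 4 a lower effect at 24 h (10 and 5 adjusted over the list alone). Cholesterol synthesis genes had a higher effect at 24 h, 9 of 25 with none lower (18 and 0 adjusted over the list alone). Hmgcs1 was at 1.65 ± 0.31, Msmo1 at 1.56 ± 0.26, Stard4 at 1.19 ± 0.19 and Nsdhl at 1.09 ± 0.21. On slide 2, the only slide with all 4 groups, Hmgcs1 and Msmo1 were at 0.66 each, Nsdhl at 0.35 and Stard4 at 1.38. Nrf2 targets had a lower effect, 5 of 28 with none higher (9 lower and 1 higher adjusted over the list alone). Gclc was at -2.06 ± 0.23, Srxn1, the sulfiredoxin, at -1.82 ± 0.19, Cbr3 at -1.80 ± 0.20 and Txnrd1, a thioredoxin reductase, at -1.07 ± 0.16. AhR targets had a lower effect, 4 of 19 with none higher (6 and 0 adjusted over the list alone): Cyp1a1, Ugdh (-1.66 ± 0.15), Ahrr, the receptor's repressor, whose controls were not well above background at either time, so that no size is given, and Nqo1 (-1.03 ± 0.17). Among the largest other differences were Cyp4a14 (2.77), Mid1ip1 (2.16) and Klf10 (2.07), with a higher effect at 24 h, and Pdk4 (-2.33) and Nfil3 (-2.07), with a lower one. For Mdm2 the difference was -0.42 ± 0.10 (adjusted p = 0.05 after rounding, just under the threshold).

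As sets, the cholesterol list (adjusted p = 1.3e-12, adjusted p = 0.26 with an estimated correlation), the Nrf2 list (adjusted p = 2.5e-08, adjusted p = 0.024 with an estimated correlation) and the AhR list (adjusted p = 3.1e-06, adjusted p = 0.024 with an estimated correlation) differed between the times. The other 6 calls, each with adjusted p = 0.80 with an estimated correlation, were the clock (0.02), CAR and PXR targets (lower, 0.02, none past singly), interferon response (higher, 0.02, none past singly), general hepatocyte markers (lower, 0.038, none past singly), male-biased genes (lower, 0.043; Nat8f5 -1.83 ± 0.28) and fatty acid and triglyceride synthesis (higher, 0.046; Srebf1 1.47 ± 0.18). Each of those 6 was lost when certain single arrays were left out, and each in other settings as well, the interferon call with fry in place of camera (0.26). Without 1 array, adjusted p rose to as much as 0.071 for the clock (without control_4h replicate 5), 0.40 for CAR and PXR targets and for fatty acid synthesis (without control_24h replicate 9), 0.061 for interferon (without BaP_24h replicate 9) and 0.37 for the hepatocyte and male-biased lists (without control_24h replicate 10). Sets not called were p53 targets (adjusted p = 0.94; median 0.07, mean -0.02), DNA repair (0.68), cell cycle (0.44), conjugation (0.29), PPARa (0.90), bile acid (0.90; median -0.06, mean 0.03) and glucose (0.19). Nor were acute phase (0.68), unfolded protein (0.057), heat shock (0.23), female-biased (0.88) or pericentral (0.39) sets called. The same held for periportal (0.071), Kupffer (0.76), neutrophil (0.39), lymphocyte (0.44), erythroid (0.22), endothelial (0.90; median 0.01, mean -0.04), stellate (0.88; median 0.05, test down), cholangiocyte (0.68), acinar (0.90) and adipose (0.88; median 0.01, mean -0.12).

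**Figure D4:**
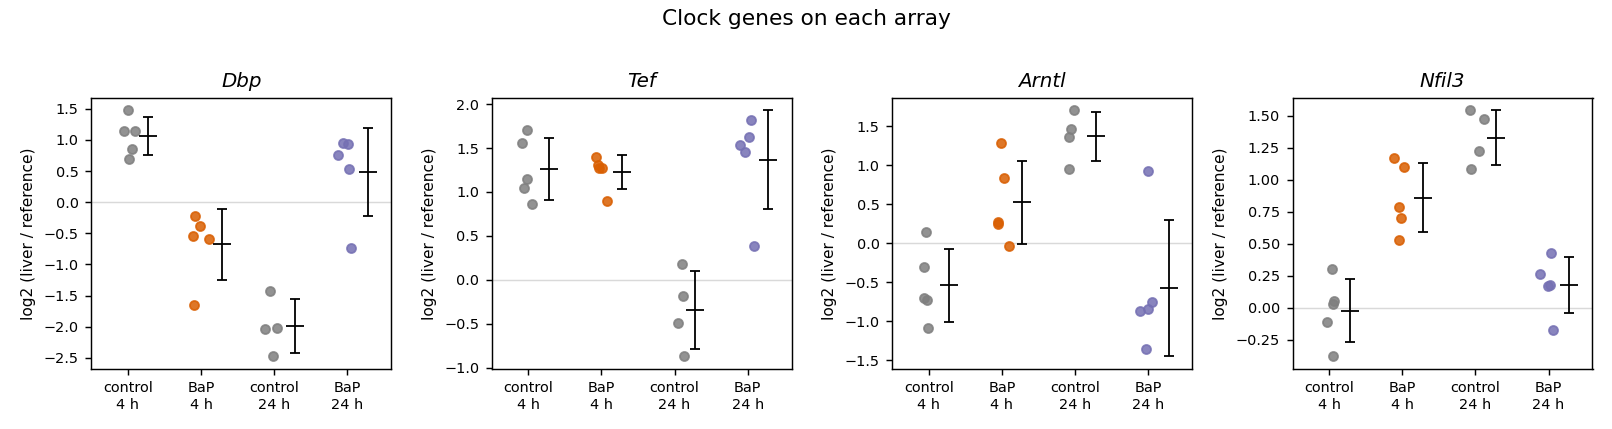
Normalized log2 ratio of liver to reference (vertical axis) for 4 clock genes in the 4 groups (horizontal axis), 1 dot per array, with mean and SD. Dbp on the controls lay between 0.70 and 1.48 at 4 h and between -2.48 and -1.43 at 24 h, and on the BaP arrays between -1.66 and -0.22 at 4 h and between -0.74 and 0.95 at 24 h.

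Of the lists without a call, the periportal and unfolded protein lists were called as lower in 6 and 4 planned settings, with adjusted p down to 0.00042 (no slide term) and 0.0079 (the authors' ratios). With the 2 arrays remade, both were called (0.023 and 0.012). The replicate block called cell cycle (0.0073) as higher and conjugation (0.041), erythroid (0.015) and glucose (0.022) as lower. With no slide term, cell cycle (0.00019) was called as higher and glucose (0.0056), erythroid (0.0059), heat shock (0.016), conjugation (0.02) and bile acid (0.037) as lower. Pericentral markers were called as higher in the Cy5 channel alone (0.0095) and after scaling (0.031), and heat shock as lower with median centring (0.043). The periportal list was also called without BaP_4h replicate 1 (0.046), BaP_4h replicate 6 (0.033), BaP_24h replicate 13 (0.038), BaP_24h replicate 12 (0.023), control_4h replicate 5 (0.0029), BaP_4h replicate 5 (0.039) or control_24h replicate 12 (0.041). The unfolded protein list was called without control_24h replicate 9 (0.0038), BaP_24h replicate 9 (0.011), BaP_24h replicate 10 (0.04), control_4h replicate 6 (0.038), BaP_4h replicate 6 (0.033), BaP_24h replicate 14 (0.047) or control_4h replicate 7 (0.02). Heat shock was called as lower without BaP_24h replicate 10 (0.041), glucose as lower without control_4h replicate 5 (0.02), erythroid markers as lower without BaP_24h replicate 12 (0.038), and cell cycle as higher without BaP_24h replicate 12 (0.038) or control_24h replicate 12 (0.033). The difference of effects passed for 360 genes, 175 higher and 185 lower at 24 h, and all 38 named ones had the same direction on slide 2, the only slide that held all 4 groups. Those arrays had also helped to pick the 38, so this is not independent support. Without the slide term 142 passed. Leaving out 1 array gave 124 (control_4h replicate 5), 155 (BaP_24h replicate 12), 205 (BaP_4h replicate 2), 208 (control_24h replicate 10), 211 (control_4h replicate 2), 224 (BaP_24h replicate 10) or 547 (control_4h replicate 6). Across all settings other than leaving out 1 array, 3 of the 38 kept their call (Arntl, Nfil3 and Pdk4). Median centring kept 4 and the fit with no slide term 21. Of the 38 named genes 24 stayed past the threshold with any array left out, and the highest adjusted p among the other 14 (Arrdc3, Ccnd1, Dnajb9, Fabp4, Hmgcs1, Lipe, Lyve1, Mdm2, Nsdhl, Ppp1r3b, Sel1l, Tbx3, Trib3 and Ugt2b35) was 0.20, for Dnajb9 without BaP_24h replicate 12. Across genes the log2 fold changes at 4 h and 24 h had Pearson r = 0.246 and Spearman rho = 0.118; genes are not independent replicates, and shared slide terms alone gave r = -0.06. Of the genes called at either time, 68 were higher at both (7.1 if independent), 73 lower at both (10), 21 higher at 4 h and lower at 24 h (8.4) and 15 the reverse (8.5).

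The control mice gave the change with time after the last dose of corn oil, 24 h against 4 h. Effects of the oil and of the hour of the day could not be separated from it. The same 24 h control arrays entered this comparison with a plus sign. They entered the BaP comparison at 24 h and the difference of effects with a minus sign. Opposite changes there rest in part on the same arrays and are not independent findings. Examples are the metallothioneins, Cyp4a14, Tef and the male-biased, hepatocyte and periportal lists. Dbp was 8.05-fold lower at 24 h (log2 -3.01 ± 0.23, adjusted p = 2.9e-05, n = 4 and 5 arrays), and Arntl was 3.73-fold higher (1.90 ± 0.26, adjusted p = 0.0018). Clock genes fell on balance, 10 of 20 with 2 higher (11 and 4 adjusted over the list alone). Tef was at -1.61 ± 0.23 and Usp2 at -1.36 ± 0.29 (set adjusted p = 0.00013, adjusted p = 0.42 with an estimated correlation). The PPARa list also fell, 7 of 34 with 1 higher (10 and 1 adjusted over the list alone). Cyp4a14 was at -2.09 ± 0.28, Acot1 at -0.95 ± 0.17, Angptl4 at -0.91 ± 0.19 and Cidec at -0.87 ± 0.13 (adjusted p = 0.00013, adjusted p = 0.42 with an estimated correlation). Genes of the unfolded protein and integrated stress response rose, 4 of 19 with none lower (7 and 1 adjusted over the list alone). They were Dnajb9, a chaperone of the endoplasmic reticulum, at 1.13 ± 0.14, Herpud1 at 0.70 ± 0.15, Sel1l at 0.47 ± 0.09 and Dnajc3 at 0.45 ± 0.11 (adjusted p = 0.00053, adjusted p = 0.43 with an estimated correlation).

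Of 10 heat shock and metallothionein genes Hspa1a (1.41 ± 0.27) and Hsph1 (1.22 ± 0.26) rose and Mt2 (-1.77 ± 0.41) and Mt1 (-1.59 ± 0.29) fell. The set leaned up (adjusted p = 0.037, adjusted p = 0.61 with an estimated correlation, 0.15 without control_4h replicate 2). Cyp26a1, which degrades retinoic acid (2.82 ± 0.38), Ppp1r3b, a regulator of glycogen synthesis (1.74 ± 0.17), Chka (1.50 ± 0.25), Ddc (1.50 ± 0.25) and Pfkfb3 (1.26 ± 0.17) rose, and Rgs16 fell by 2.46 ± 0.51. Interferon response genes fell (Usp18 -0.63 ± 0.09, lower among 21; adjusted p = 0.0032, adjusted p = 0.53 with an estimated correlation). Male-biased genes rose (Nat8f5 1.18 ± 0.19, higher among 19; adjusted p = 0.00084, adjusted p = 0.61 with an estimated correlation, 0.07 without control_24h replicate 10 and 0.96 after scaling between arrays). General hepatocyte markers rose as a set with none of 15 past singly (adjusted p = 0.00091, adjusted p = 0.61 with an estimated correlation), but the direction turned after scaling between arrays (adjusted p = 0.96) and in the Cy5 channel alone (0.66). The call was lost without control_24h replicate 10 (0.079) or control_4h replicate 2 (0.06), and in the authors' ratios (0.061, but not with the 2 arrays remade). Periportal markers rose with none of 18 past singly (adjusted p = 0.0055, adjusted p = 0.63 with an estimated correlation), but the direction turned after scaling between arrays (adjusted p = 0.35). The call was lost without control_24h replicate 10 (0.11) or control_4h replicate 2 (0.06). It was also lost in the Cy5 channel alone (0.75) and in the authors' ratios (0.53, but not with the 2 arrays remade). Cholesterol synthesis (higher) and adipose markers (lower; Cidec) were just under the threshold at adjusted p = 0.05, with adjusted p = 0.68 and adjusted p = 0.43 with an estimated correlation. They were lost without any of 9 and 12 single arrays, with adjusted p up to 0.85 (control_24h replicate 10) and 0.09 (control_24h replicate 12). Among other settings, the cholesterol call was lost after scaling (0.62) and in the scanner software's log ratios (0.18). The adipose call was lost with no slide term (0.21), in the Cy5 channel alone (0.13) and in the fit of 2 groups (0.11).

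Sets not called for time in the controls were AhR (adjusted p = 0.96; Ugdh 0.45 ± 0.11; median -0.02, mean 0.02), p53 (0.12; Sesn2 -0.47 ± 0.09, Sulf2 -0.47 ± 0.10), Nrf2 (0.44; Gclc 0.65 ± 0.16), DNA repair (0.50), cell cycle (0.24; Ccne1 -0.73 ± 0.12), and CAR and PXR (0.099; Por -0.99 ± 0.20). The test also made no call for conjugation (0.10; Ugt2b35 0.73 ± 0.17, Ugt2b34 0.61 ± 0.13), fatty acid synthesis (0.33), bile acid (0.10), glucose (0.10; Slc37a4 -0.50 ± 0.10), and acute phase (0.34; Cebpb -0.63 ± 0.13). The others without a call were female-biased (0.14), pericentral (0.35), Kupffer (0.96), neutrophil (0.94), lymphocyte (0.88), erythroid (0.28; Tfrc 0.68 ± 0.11), endothelial (0.10), stellate (0.099; Lrat 0.80 ± 0.19), cholangiocyte (0.31) and acinar (0.88). With 1 array left out, calls were gained without control_4h replicate 5 (CAR and PXR 0.023, bile acid 0.023, conjugation 0.027, endothelial 0.032 and glucose 0.011, all higher). Without control_24h replicate 12 they were CAR and PXR (0.0063), conjugation (0.023), endothelial (0.012) and glucose (0.018), all higher, and cell cycle (0.00028, lower). Others were stellate markers without control_4h replicate 1 (0.0035, lower), female-biased genes without control_24h replicate 9 (0.017, lower), CAR and PXR without BaP_4h replicate 6 (0.045, higher) and endothelial markers without BaP_24h replicate 12 (0.046, higher). Cell cycle genes were called as higher after scaling (0.0061) and as lower with no slide term (0.00084). Female-biased genes were called as lower in the authors' ratios (0.035, but not with the 2 arrays remade), after scaling (0.0017) and in the Cy5 channel alone (0.027). Fatty acid synthesis was called as lower after scaling (0.0064) and in the Cy5 channel alone (0.048), stellate markers as lower in the scanner software's log ratios (0.039) and with no slide term (0.0087), and p53 targets as lower with no filter on dim probes (0.032). CAR and PXR targets were called as higher with only probes above background on all 19 arrays (0.018), conjugation with median centring (0.035), and conjugation (0.028), glucose (0.011) and bile acid (0.012) with no slide term. In all, 405 of 15728 genes passed, 206 higher and 199 lower, and all 36 named ones moved the same way on the 3 slides that held both control groups. Those arrays had also helped to pick the 36, so this is not independent support. Without the slide term 197 passed, a fit of these 2 groups alone gave 164, and leaving out 1 array gave 143 (control_4h replicate 5), 145 (control_24h replicate 12), 165 (control_4h replicate 1), 208 (control_24h replicate 10) or 211 (control_4h replicate 2). Across all settings other than leaving out 1 array, 3 of the 36 kept their call (Arntl, Chka and Dbp). Median centring kept 4 and the fit of 2 groups 21. With each array left out in turn 17 of the 36 stayed past the threshold every time. The highest adjusted p among the other 19 (Angptl4, Cebpb, Dnajc3, Gclc, Herpud1, Hspa1a, Hsph1, Lrat, Mt1, Mt2, Por, Rgs16, Sel1l, Slc37a4, Sulf2, Ugdh, Ugt2b34, Ugt2b35 and Usp2) was 0.19, for Gclc without control_4h replicate 5.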

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

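All tests in this part other than the difference of effects and the 100 chance splits were chosen only after the results were seen.

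Differences of the BaP effect between 24 h and 4 h were looked for as signs of a time-dependent effect, and 360 genes passed. The clock genes Dbp (4.36), Bhlhe40 (1.88), Arntl (-3.27) and Nfil3 (-2.07) were among them. Cholesterol synthesis genes had a higher effect at 24 h in the fit: Hmgcs1 (1.65, on slide 2 0.66), Msmo1 (1.56, on slide 2 0.66), Stard4 (1.19, on slide 2 1.38) and Nsdhl (1.09, on slide 2 0.35). So did Srebf1 (1.47), Mid1ip1 (2.16), Klf10 (2.07), Arrdc3 (1.97), Cyp4a14 (2.77), Cyp4a31 (1.38), Tbx3 (1.85), Ccnd1 (1.25), Ccne1 (1.03), Trib3 (1.16) and Lipe (0.59). AhR and Nrf2 targets had a lower effect at 24 h: Cyp1a1 (-6.19 in the fit) and Ahrr (-1.30 in the fit), neither an exact size because the 24 h controls were not well above background, Ugdh (-1.66), Nqo1 (-1.03), Gclc (-2.06), Srxn1 (-1.82), Cbr3 (-1.80) and Txnrd1 (-1.07). So did Mdm2 (-0.42), Pdk4 (-2.33), Ppp1r3b (-1.07), Ugt2b35 (-1.36), Nat8f5 (-1.83), Tfrc (-1.33), Lyve1 (-0.95), Emcn (-0.74), Fabp4 (-0.81), Dnajb9 (-0.79) and Sel1l (-0.69). The 9 lists with a difference had adjusted p = 3.1e-06 (AhR), 2.5e-08 (Nrf2), 0.02 (CAR and PXR), 0.046 (fatty acid and triglyceride synthesis), 1.3e-12 (cholesterol synthesis), 0.02 (interferon), 0.02 (clock), 0.043 (male-biased) and 0.038 (hepatocyte); only the AhR and Nrf2 lists kept it with an estimated correlation (0.024 each).

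Single arrays far from the other arrays of their group were sought with a gap statistic, the distance to the nearest neighbour over the range of the group, for 143 named genes. It passed the tabulated limit for the size of the group in 38 of 571 combinations, and chance flags about 1 in 20 groups. BaP_24h replicate 9 stood apart for Dbp (0.76), Arntl (0.73), Per1 (0.72), Usp2 (0.78), Tef (0.75), Tsc22d1 (0.80), Ccne1 (0.73), Clpx (0.76) and Chka (0.88). BaP_4h replicate 2 did for Nr1d1 (0.73), Dbp (0.74), Per1 (0.80), Tef (0.73) and Herpud1 (0.74). The 24 h control replicate 9 did for Tsku (0.87), Myc (0.86), Ercc3 (0.85) and Ccnd1 (0.89), and the 4 h control replicate 7 for Myc (0.78), Tsc22d1 (0.76) and Nr0b2 (0.88). Fewer genes stood apart on BaP_24h replicate 12 (Slc25a30 0.82, Bax 0.73, Ahrr 0.79), and BaP_24h replicate 14 (Nkd1 0.73, Eng 0.79, Adgrv1 0.72). So it was on the 24 h control replicate 13 (Rgs16 0.88, Klf10 0.96), BaP_4h replicate 5 (Arrdc3 0.92, Sel1l 0.81) and the 24 h control replicate 10 (Tbx3 0.88, Cyp4a31 0.91). Single genes did on the 24 h control replicate 12 (Nat8f5 0.83), BaP_24h replicate 10 (Tfrc 0.74), the 4 h control replicate 5 (Slc16a5 0.86), BaP_4h replicate 6 (Acot3 0.78) and BaP_4h replicate 1 (Ttr 0.72).

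Chance alone was weighed with 100 splits of the arrays into groups of the same size, the real split included. At 4 h 1002 genes passed against at most 3 in another split, which argues against chance as far as 100 splits can show. The splits moved arrays between slides, so they did not keep the balance of the real groups over the slides. At 24 h 532 passed against at most 531, reached only by the split that moves BaP_24h replicate 9 to the controls, the next highest being 322. The difference of effects gave 360 against 135. Time in the controls gave 405 against 355, reached by moving the 4 h control replicate 6, the next highest being 319. In each of these comparisons the real split alone, 1 of 100, reached its count. For the difference of effects the splits also broke up the BaP effect at each time. Beating them therefore does not by itself exclude chance for a difference between the times. At 24 h and for control time a split that moved 1 array came close to the real count. Such a split kept most of the real grouping, so the count did not clearly exclude chance there. The number of called lists was 10, 10, 9 and 10, against a median of 8, 6, 6 and 6 in the other splits. It was reached in 28, 25, 30 and 20 of 100 splits with at most 16, 14, 18 and 15. The correlation of the fold changes at 4 h and 24 h, 0.246, was reached in 24 of 100 with at most 0.849, so chance was not excluded for them.

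The reference channel was also examined by itself. Each channel alone was rebuilt from the loess ratio and the mean log intensity, the latter quantile-normalized between arrays. In the authors' per-array tables the normalized reference signal had r = 0.415 with the raw reference signal of its own array on BaP_4h replicate 5 and 0.398 on the 24 h control replicate 12. The reference channel alone, which should not respond to treatment, differed for Cyp1a2 (3.40), Cyp1a1 (1.10) and a probe without a gene name (-0.35) at 4 h. At 24 h it differed for Cyp1a2 (3.47), Cyp2a4 (2.13), Cyp2a5 (2.00), Adh1 (1.22) and Elovl3 (-3.56), and for control time for Slc25a47 (-1.75). The liver channel alone and the ratio were at 2.50 and 0.37 for Cyp2a4, at 2.00 and -0.01 for Cyp2a5 and at 0.58 and -0.64 for Adh1, so the ratio can hide or turn a change in the liver channel. Over all genes, which are not independent replicates, the changes of the 2 channels had r = 0.363 to 0.494 in the 4 comparisons. Both channels were rebuilt from the same ratio and mean intensity of each spot, so this correlation does not show a response of the reference.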

How the results depend on the processing

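The other settings were chosen ahead of the results, apart from those added after seeing the data, and the cause of a change was not tested. Against 1002, 532, 360 and 405 genes (4 h, 24 h, difference, control time), median centring gave 40, 9, 7 and 10, no slide term 514, 213, 142 and 197, and array weights, which did not converge, 2163, 2136, 1541 and 1846. The fit of 2 groups alone gave 662, 1 and 164, the scanner software's log ratios 353 (24 h) and 227 (difference), and the replicate block 261 and 167. Called lists, 10, 10, 9 and 10, became 2, 0, 2 and 0 with an estimated correlation, 5, 3 and 2 (24 h, difference, control time) with fry, 16 and 15 (24 h, difference) with no slide term, 5 (difference) with the scanner's log ratios and 4 (difference) with probes above background on all arrays. Directions turned for Bax at 4 h (0.08 in Cy5 alone, 0.01 with no slide term, 0.01 with the replicate block, 0.09 in the fit of 2 groups), Hsd3b4 at 4 h (0.04, scanner), Sel1l (-0.01) and Ly6c1 (-0.17) at 4 h at another probe, Ly6c1 (-0.04) and Nsdhl (-0.19) at 24 h at another probe. They also turned for Cdkn1a at 24 h (-0.02 in Cy5 alone, -0.05 with array weights) and Saa2 at 24 h (0.34 in the authors' ratios, 1.35 in Cy5 alone). Cyp1a2 turned at 4 h (0.51, 2.79 and 0.18 in the authors' ratios, in Cy5 alone and with median centring) and at 24 h (0.46, 2.81 and 0.12 in the authors' ratios, in Cy5 alone and at its other probe). With 2 arrays of the authors' table remade from their own channels, neither Saa2 nor Cyp1a2 turned. That setting mixes loess ratios on those 2 arrays with the authors' normalization on the others. It is therefore not the authors' ratios with an exchange undone. Lists turned in direction were glucose metabolism at 24 h (adjusted p = 0.99, Cy5 alone) and, for control time, periportal (0.35, scaling) and hepatocyte markers (0.96 with scaling, 0.66 in Cy5 alone). With 1 array left out, Cdkn1a at 24 h lay between -0.21 (BaP_24h replicate 9) and 0.26 (BaP_24h replicate 12) and Cyp1b1 at 24 h between -0.03 (control_24h replicate 9) and 0.24 (BaP_24h replicate 12). Leaving out 1 array gave 581 to 1193 genes at 4 h (BaP_4h replicate 5, control_24h replicate 9), 233 to 761 at 24 h (BaP_24h replicate 12, control_24h replicate 9), 124 to 547 for the difference (control_4h replicate 5, control_4h replicate 6) and 143 to 576 for control time (control_4h replicate 5, control_24h replicate 9). It gave 9 to 11, 8 to 11, 4 to 12 and 4 to 15 lists, and a correlation of 0.158 to 0.299. Probes close to background, with Cy5 medians of 70.2 to 89.8 over 58.0 to 61.0, limit fold changes of dim genes.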

Other observations

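All tests of the patterns below were chosen only after the results were seen.

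Genes that respond to time in the control mice were compared between the arms, with examples chosen after their values were seen. Outside the clock list, 235 of 393 genes called for control time moved the same way from 4 h to 24 h in both arms, among them Pfkfb3 (1.26 in the controls and 1.43 with BaP), Angptl4 (-0.91 and -1.41) and Acot1 (-0.95 and -1.64). Others turned, such as Pdk4 (0.84 and -1.49) and Klf10 (-1.18 and 0.89). Of 20 measured clock genes 15 had opposite signs in the arms, such as Arntl (1.90 and -1.37) and Nfil3 (1.33 and -0.73), some with little change with BaP, such as Tef (-1.61 and 0.25 ± 0.22). Cry2 (-0.85 and -0.30) moved the same way in both.

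The first pattern is the turned clock. Exchanged time labels in 1 arm would turn the time effects of that arm. Over the 393 genes called for control time outside the clock list, the time effects of the 2 arms had r = 0.216. With 1 array left out it lay between 0.107 and 0.268, against -0.852 over 12 clock members. Genes are not independent replicates, the 393 were picked in the control arm, and BaP can itself change time effects. So weak a correlation therefore does not settle whether labels were exchanged. A single array alone is argued against by the time effects of the arms over all 20 measured clock genes, with r = -0.846, and between -0.880 and -0.787 with 1 array left out. The difference of effects passed for 11 clock genes but for only 5 without control_4h replicate 5, while its median size over those 11, which the same test picked, was 1.83 and stayed at 1.69 or more with any array left out. A different hour of killing in the 2 arms could not be told apart from an effect of BaP, because the labels give no hour, and Dbp moved by 1.36 with BaP against -3.01 in the controls.

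The second pattern is in the authors' normalized reference channel. On BaP_4h replicate 5 it had r = 0.415 with its own raw reference and 0.988 with that of control_24h replicate 12, which in turn had 0.398 with its own and 0.990 with that of the former; the other 17 arrays matched their own best. The residual SD against the raw reference of the other array was 0.00478, within the range of the other 17, which fits an exchange of the 2 channels before normalization. Exchanged raw columns are argued against by the raw liver and raw reference signals of the same array, with r = 0.566 and 0.526, against at most 0.303 and 0.311 with another array. The fold changes above come from the scanner files, and only values given for the authors' ratios use these 2 arrays as they stand in that table.

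The third pattern is Cyp1a2, lower in the ratio while both channels rose. At the brightest probe the Cy3 channel alone rose by 3.40 ± 0.18 at 4 h and 3.47 at 24 h, and the Cy5 channel by 2.79 and 2.81. These channel values were rebuilt after loess, so the gap between them restates the loess ratio. Median centred without loess, the Cy3 channel rose by 3.09 at 4 h and 3.18 at 24 h, and the Cy5 channel by 3.24 and 3.14. The drop below 0 goes with loess: with median centring the ratio was 0.18 ± 0.23 and -0.04 ± 0.23, against -0.60 and -0.66. A rise of the ratio hidden by loess is argued against by the same values at that probe but stays open at the other, at 0.20 ± 0.31 and 0.60 ± 0.31, and saturation is argued against by 0 saturated Cyp1a2 spots. Because both channels rose together at the brightest probe, the ratio did not follow the rise of the liver signal. The counts of Cyp1a2 as lower in the AhR list therefore hold for the ratio only. How liver treatment came to change a reference channel was not decided.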
